A study of Mus musculus with 12 samples.

How the data were processed

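Accessible chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in early T progenitors sorted from mouse fetal thymus. Per the labels, the sorted cells lacked CD4, CD8 and lineage markers, carried CD44 and high levels of Kit, and lacked CD25, and the strain was C57BL/6. The 12 libraries formed 6 groups of 2 libraries, named here by genotype. WT had no allele change. E47KO lacked E47, one of the E protein transcription factors made from the E2A gene Tcf3. N1En_del carried a deletion that the labels call N1En, and N1En_del_E47KO carried both changes. E2A_HEB_dKO carried floxed Tcf3 and Tcf12, which encode E2A and HEB, with Il7r-Cre, and E2A_HEB_dKO_NICD added the Notch intracellular domain (NICD), the active form of the Notch receptor. Group and replicate were read from the sample titles. No label said that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. In E47KO and in N1En_del, 1 library listed 22 peaks on chromosome Y and the other 0. This argues against technical repeats of 1 sample in these groups and leaves the others open.

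Per the submitters' processing notes, the authors used bcl2fastq, Bowtie2 and HOMER on genome build mm9. The HOMER version, its command and its thresholds are not given in the sources used here, and neither is any shift of reads for the Tn5 cut site. The deposited lists held 1 list of peaks for each library, called separately, with every peak 150 bp wide. Per the file headers, the normalized tag count is a signal: tags in the peak scaled by 1 constant for each library. The scale itself was not recorded. The deposited fold over the local background is a ratio of the tags in a peak to those around it, and the lowest ratio listed was 4 in each of the 12 lists. No list held 2 peaks whose starts were under 300 bp apart. The deposited score of the peak caller, the p-value against the local background and the clonal fold (a ratio for repeated tags), all named per the file headers, were not used in any comparison.

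Normalized tag counts under 10 rose in equal steps, and 100% of them lay within 0.0051 of a whole multiple of the step fitted in each library, which gave the relative depth of the libraries, from 1.0 for E47KO replicate 1 to 1.88 for N1En_del_E47KO replicate 1. The lowest peak listed held between 14 and 21 tags. No total was recorded, so the values were used as normalized values and no count test was run.

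Peaks less than 150 bp apart were joined across the 12 lists into 140247 consensus regions with a median width of 184 bp. This joining distance was set after the minimum spacing within the lists had been seen. A library's value in a region was its highest normalized tag count there. Values were taken to log2. A library without a peak in a region received its own floor, the lowest value in its list (3.11 to 4.55). Each library was centred on its median over the 35082 regions with a peak in all 12 libraries. Those medians lay between -0.31 and 0.54 around their mean on the log2 scale, highest in E47KO replicate 2. A region was tested where at least 1 of the groups compared had a peak in both libraries. The test was limma 3.58.1 in R 4.3.3 (linear model over all 6 groups, contrasts, empirical Bayes with trend and robust options, residual df 6, prior df 16.5), with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. A log2 fold change against a group without a peak depends on the floor and is not a bound, so for such regions the text says that no peak was listed.

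Peaks were counted as lost where both reference libraries and neither mutant library listed one, and as gained in the opposite case. The alleles were checked by counting the regions that lacked a peak in all 4 libraries with an allele change and had one in the other 8, over all 495 splits of the 12 libraries, and, added after the data had been seen, over the 15 splits that keep groups whole. The groups, the comparisons, the tests, the rule for naming regions and most alternatives were fixed before the data were examined. The rule named, for each comparison, the 10 regions with the largest fall and the 10 with the largest rise that had a peak in both libraries of the higher group. All 140 entries it gave, 85 distinct regions, were regions where the lower group listed no peak, and 45 of the 85 had another peak of that group within 1000 bp. The report therefore names from this set only regions away from both listing limits in the lower group, and the closing section adds 2 interaction regions that lie near them. The 2 regions of chromosome 1 named there lie away from both limits in WT, but chr1:24619885–24620036 has a peak of other groups 376 bp away. It adds the regions with the largest changes among those with a peak in all 4 libraries compared, which were chosen after their values were seen.

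The tests were checked on data simulated from these libraries with 4000 regions changed, 4-fold or 2-fold. For the 5 comparisons with WT, between 88.2% (E2A_HEB_dKO) and 97% (E47KO) of the 4-fold changes and between 64.5% and 72.1% of the 2-fold changes were recovered. False calls made up 3.6% to 6.1% of the calls, except for E47KO, where they made up 23.2%. There, 911 unchanged regions were called lower, because the centred floor of E47KO lay 0.57 log2 units under that of WT. Counts of calls under both the libraries' own floors and 1 shared floor are therefore given beside the counts against WT, with false calls of 1.3% to 4.1% in the same simulations. The simulated lists held neither the minimum distance between peaks nor the minimum fold over the local background. Their spread came only from regions listed in all 12 libraries. The share of false calls in the real lists may therefore be higher.

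Alternatives were values as deposited without centring, regions with a peak in all libraries compared, a filter on low values, the replicate number as a block, a joining overlap of 50%, stricter peaks, lists cut to equal length and each library left out. Added after the data had been seen were 1 shared floor, joining by an overlap of 1 bp, regions with no other region within 500 bp, autosomes, regions with a local fold of at least 8, and leaving out libraries for the overlaps between comparisons and the allele check. Gene lists and sequence motifs fixed beforehand were not analysed here, because they need the mm9 annotation and sequence, which were not used here. Regions are given by mm9 position (1-based), and no gene was assigned to them. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R with statmod 1.5.0 and data.table (version 1.17.8), were used.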

Results

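Chromatin accessibility was compared between early T progenitors of 6 genotypes, with 2 ATAC-seq libraries for each. The lists held between 57691 peaks (E2A_HEB_dKO replicate 1) and 93785 peaks (E47KO replicate 2). WT had 74897 and 67339 peaks, N1En_del 86784 and 75364, N1En_del_E47KO 69252 and 77448, and E2A_HEB_dKO_NICD 71672 and 78257. Of the 140247 consensus regions, 35082 had a peak in all 12 libraries and 30518 in 1 library only. The deepest library held 1.88 times the tags of the shallowest for the same normalized value, and the lowest peak of each list rested on 14 to 21 tags. Peaks on chromosome Y were listed in both WT libraries (18 and 26), both E2A_HEB_dKO_NICD libraries (22 and 26), E47KO replicate 1 (22) and N1En_del replicate 2 (22), and the other 6 libraries listed 0. The comparisons of WT or E2A_HEB_dKO_NICD with E2A_HEB_dKO, and of WT with N1En_del_E47KO, therefore set libraries with Y peaks against libraries without them. Values below are normalized tag counts as means ± SD of 2 libraries, and fold changes are log2 differences after centring ± SE from limma.

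Over the 35082 regions present in all libraries, E47KO, N1En_del_E47KO and E2A_HEB_dKO lay on the opposite side of PC1 from WT and N1En_del. PC1 held 33.9% of the variance and placed WT and N1En_del between -48.8 and -38, E47KO at 26.8 and 17.6, N1En_del_E47KO at 35.6 and 31.9 and E2A_HEB_dKO at 63.2 and 39.6. E2A_HEB_dKO_NICD stood between these sets on PC1 (-16.5 and -20.8) and at the lower end of PC2 (-42.7 and -45.7, 17.1% of the variance). On PC2 E2A_HEB_dKO (-30 and -22.3) lay on the side of E2A_HEB_dKO_NICD, whereas E47KO (25.8 and 11.9) and N1En_del_E47KO (30 in both libraries) lay on the other. The mean correlation across regions was 0.94 between E47KO and N1En_del_E47KO libraries, 0.931 between N1En_del_E47KO and E2A_HEB_dKO and 0.857 between WT and E2A_HEB_dKO, while libraries of the same group reached 0.937 to 0.97. These correlations are across regions, which are not independent replicates.

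**Figure D1:**
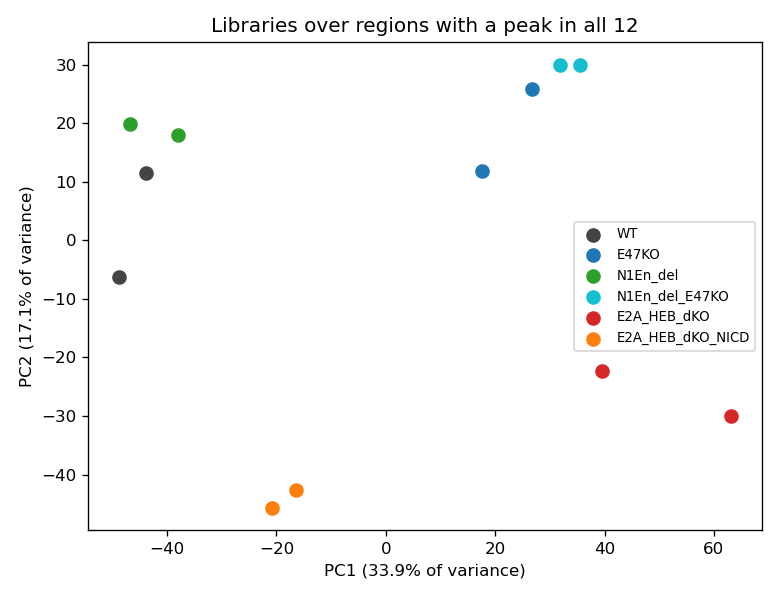
Principal components of the 12 libraries from centred log2 normalized tag counts over the 35082 regions with a peak in all of them. PC1 (33.9% of the variance) runs from WT and N1En_del at the left, between -48.8 and -38, to E2A_HEB_dKO at the right (63.2 and 39.6).

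A region on chromosome 2, chr2:26368915–26369174, was called lower than in WT in the 4 mutant groups without NICD. It held 53 ± 15 in WT, 6.89 ± 1.6 in E47KO and 8.93 ± 0.64 in E2A_HEB_dKO, and no peak was listed there in the N1En_del and N1En_del_E47KO libraries. Accessibility fell by 3.47 ± 0.33 in E47KO (adjusted p = 6.64e-07) and by 2.40 ± 0.33 in E2A_HEB_dKO (adjusted p = 4.58e-05), and both N1En groups were called lower than WT (adjusted p = 1.93e-07 and 9.55e-08). A missing peak in the N1En groups would be absent DNA if the deletion covers this segment, which these data do not decide. With NICD the region held 29.8 ± 1.3, which was 1.56 ± 0.33 above E2A_HEB_dKO (adjusted p = 0.00586). Its difference of -0.84 ± 0.33 from WT had an adjusted p of 0.109, which became 0.0359 over regions with a peak in all 4 libraries and 0.0353 with 1 shared floor. Without E2A_HEB_dKO_NICD replicate 1 the rise with NICD was 1.46 and no longer passed the threshold (adjusted p = 0.06). The region was chosen after its values were seen, although the named rule also lists it for the N1En comparisons. The nearer region chr2:26363138–26363318 had no peak in either N1En_del_E47KO library. In the groups that listed it the means ran from 18.8 ± 4.7 (N1En_del) to 23.5 ± 0.49 (E2A_HEB_dKO). A farther region, chr2:26359296–26359464, had a peak in all 12 libraries, with group means from 57 ± 5.9 (N1En_del) to 78.2 ± 2.7 (E47KO).

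**Figure D2:**
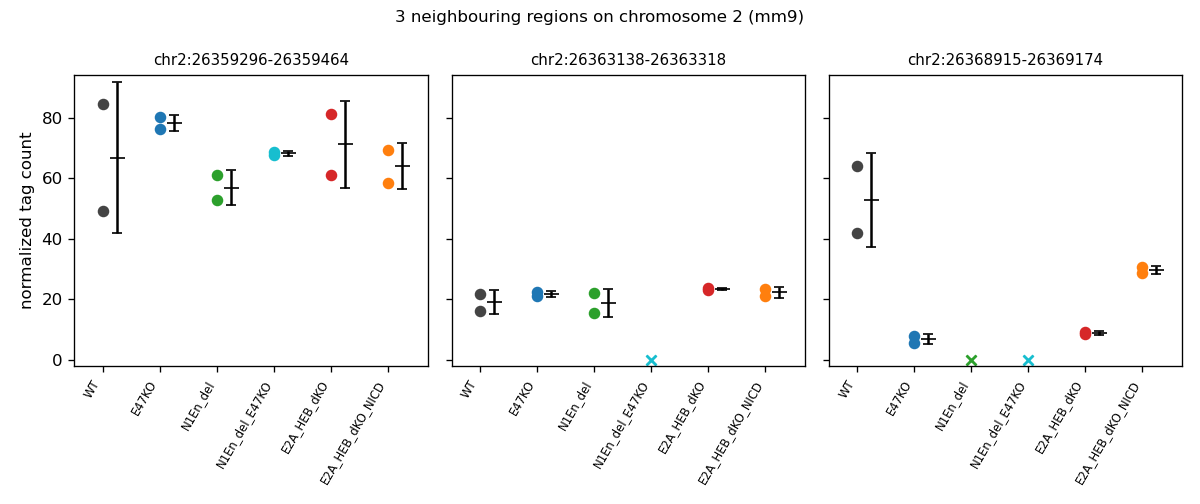
Normalized tag counts of each library at 3 neighbouring regions of chromosome 2 (mm9). Points are libraries, crosses at 0 mark libraries without a listed peak, and black bars give the mean ± SD of groups with 2 peaks; at chr2:26368915–26369174 WT lies at 63.9 and 42, E2A_HEB_dKO_NICD at 30.7 and 28.8, and N1En_del and N1En_del_E47KO list no peak.

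The comparison of E47KO with WT asked where loss of E47 alone changed accessibility. Among regions with a peak in all 4 libraries, the largest rise was at chr3:152615215–152615437, from 8.05 ± 2.9 to 50.8 ± 9.7 (2.16 ± 0.24, adjusted p = 4.62e-06), and chr5:96630596–96631107 rose from 6.75 ± 2.1 to 38.7 ± 13 (1.97 ± 0.28, adjusted p = 8.68e-05). After the chromosome 2 region, a large fall was at chr8:70237082–70237303, from 44.8 ± 9.3 to 6.46 ± 1.2 (-3.32 ± 0.34, adjusted p = 1.62e-06). Regions listed in only 1 of these 2 groups included chr2:3635240–3635406, at 83.5 ± 9.48 in E47KO with no peak in WT, and chr1:66862619–66862834, at 45.4 ± 4.1 in WT with no peak in E47KO, N1En_del_E47KO or E2A_HEB_dKO. Of 77951 regions tested, 3950 were higher and 7682 lower (11632 in all), and 3400 and 5547 were called under both kinds of floor. With the values as deposited the balance turned, to 20611 higher and 3526 lower, because E47KO values lay above the others before centring. The count was 6480 over regions with a peak in all 4 libraries (2514 higher and 3966 lower), 7360 with a joining overlap of 50%, 5748 without E47KO replicate 2, 7483 without E47KO replicate 1 and 6883 without WT replicate 2.

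The comparison of N1En_del with WT asked where the N1En deletion alone changed accessibility. The largest rise among regions with a peak in all 4 libraries was at chr11:72595708–72595944, from 6.58 ± 1.6 to 28.4 ± 1.1 (2.19 ± 0.37, adjusted p = 0.00108), and chr2:90490208–90490460 rose from 7.44 ± 3.1 to 28 ± 1.2 (2.03 ± 0.37, adjusted p = 0.0021). The latter held 7.2 ± 1.8 in E47KO and 6.85 ± 0.078 in N1En_del_E47KO. Among the same regions the largest fall was at chr17:13811775–13812094, from 26 ± 2.4 to 5.37 ± 0.3 (-2.22 ± 0.38, adjusted p = 0.00126, and 0.0612 with a joining overlap of 50%), followed by chr9:116228662–116228867, from 25.1 ± 0.57 to 5.5 ± 0.47 (-2.14 ± 0.40, adjusted p = 0.0025). In total 3682 regions were higher and 2290 lower (5972 of 73872 tested), and 3627 and 2218 were called under both kinds of floor. The count was 11358 with 1 shared floor, 3184 with a joining overlap of 50%, and 2324 over regions with a peak in all 4 libraries, where 1117 were higher and 1207 lower. It was 1883 without N1En_del replicate 1, 3322 without N1En_del replicate 2 and 2835 without WT replicate 1.

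N1En_del_E47KO was compared with WT and with N1En_del, the latter giving the effect of E47 loss on the N1En deletion background. Against WT, chr4:11420259–11420446 rose from 7.95 ± 0.38 to 30.8 ± 5.9 (2.09 ± 0.26, adjusted p = 1.76e-05) and chr2:137316413–137316640 from 7.97 ± 0.75 to 30.4 ± 2.2 (2.08 ± 0.24, adjusted p = 5.24e-06). Among regions with a peak in all 4 libraries the largest fall was at chr3:37704718–37704961, from 58.4 ± 22 to 5.26 ± 0.36 (-3.27 ± 0.26, adjusted p = 2.3e-08, and 0.0597 with a joining overlap of 50%), a region at 13.7 ± 0 in E47KO and 23.6 ± 3.5 in N1En_del. Against WT 6478 regions were higher and 8182 lower (14660 of 72534), with 5928 and 7384 called under both kinds of floor. The split was 2003 higher and 9311 lower with the values as deposited, and 5523 higher and 4276 lower over regions with a peak in all 4 libraries. The count was 7357 with a joining overlap of 50%, 4120 without N1En_del_E47KO replicate 2, 5833 without replicate 1 of that group and 6889 without WT replicate 2.

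Against N1En_del, N1En_del_E47KO rose at chr4:151482120–151482337 from 10.4 ± 3.3 to 41.3 ± 3.3 (2.12 ± 0.22, adjusted p = 2.98e-06), a region at 54.6 ± 6.7 in E47KO. It fell at chr2:170261769–170262069 from 29.2 ± 6.1 to 5.08 ± 0.59 (-2.42 ± 0.31, adjusted p = 4.25e-05) and at chr6:113467556–113468035 from 25 ± 7.7 to 4.77 ± 0.58 (-2.26 ± 0.31, adjusted p = 8.61e-05), regions at 9.14 ± 1.8 and 8.02 ± 0.68 in E47KO. At chr9:107449446–107449621 N1En_del held 37 ± 3.46 and the WT mean was 39.6 ± 8.41, while N1En_del_E47KO and E2A_HEB_dKO listed no peak. In total 4460 regions were higher and 10881 lower (15341 of 76937), with 4034 and 9975 called under both kinds of floor. The split was 2165 higher and 12458 lower with the values as deposited, and the count was 7681 over regions with a peak in all 4 libraries (3522 higher and 4159 lower) and 8418 with a joining overlap of 50%. Each library left out lowered it, to 3115 without N1En_del_E47KO replicate 2, 6204 without its replicate 1, 6174 without N1En_del replicate 1 and 8429 without N1En_del replicate 2.

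The comparison of E2A_HEB_dKO with WT asked where loss of both E2A and HEB changed accessibility. At chr5:96630596–96631107 accessibility rose from 6.75 ± 2.1 to 37.8 ± 7.4 (2.65 ± 0.28, adjusted p = 1.35e-06). The region chr16:11456371–11456686 fell from 51 ± 4.2 to 6.36 ± 0.071 (-2.86 ± 0.22, adjusted p = 1.1e-08) and held 56.2 ± 9.3 in E47KO. On chromosome 12, chr12:18616730–18616911 held 104 ± 46.9 in WT, no peak in E2A_HEB_dKO and 42.2 ± 5.02 with NICD, one of several such regions between 18 and 25 Mb that are weighed in the closing section. In total 8622 regions were higher and 10887 lower (19509 of 66403), with 8230 and 10371 called under both kinds of floor. The split was 3557 higher and 12751 lower with the values as deposited, and 6818 higher and 4536 lower (11354) over regions with a peak in all 4 libraries. The count was 10723 with a joining overlap of 50%, 7645 without E2A_HEB_dKO replicate 1 and 10750 without WT replicate 2.

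**Figure D3:**
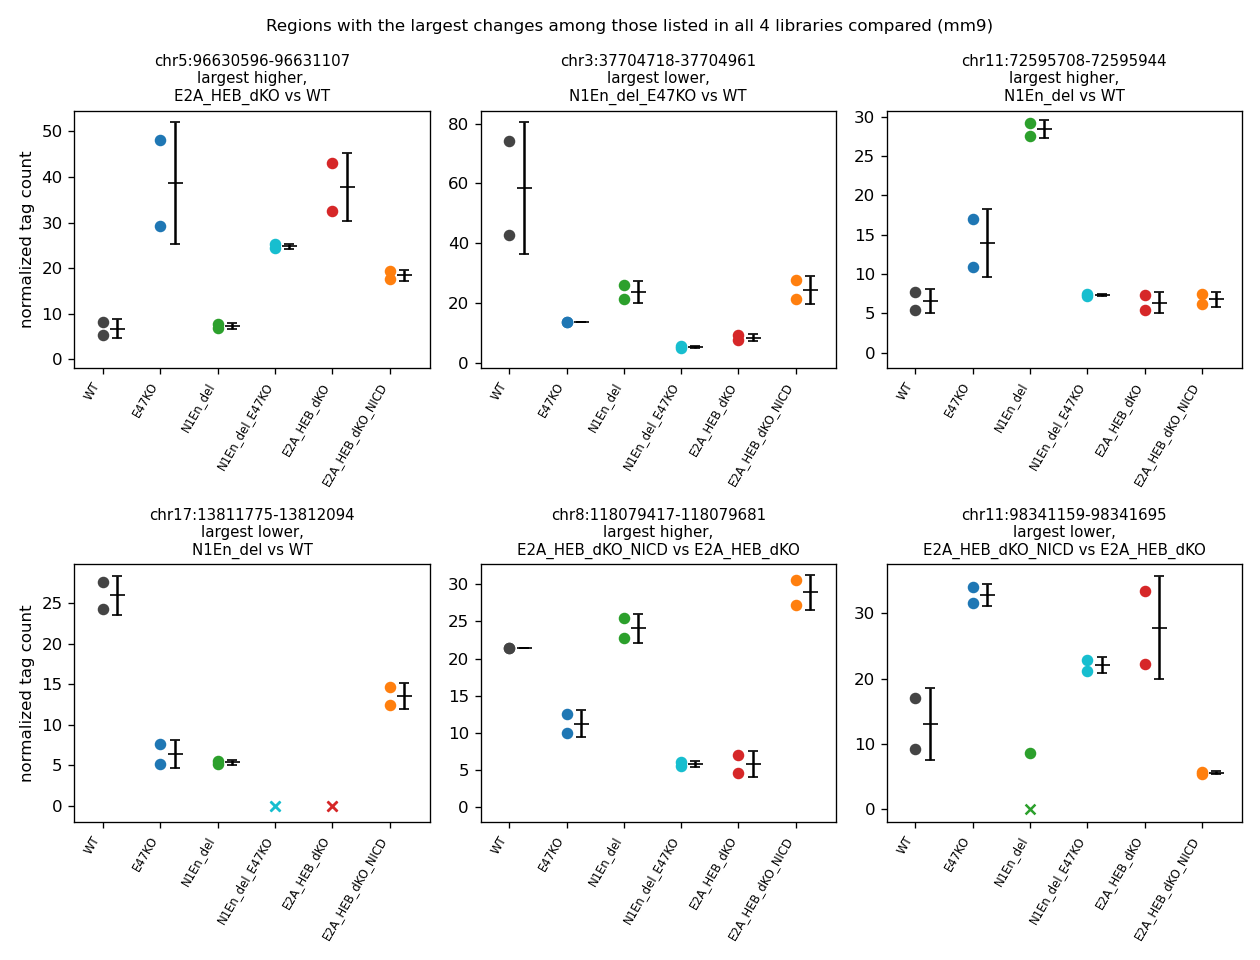
Normalized tag counts of each library at 6 regions with the largest change, among regions with a peak in all 4 libraries compared, in the comparison named above each panel (mm9). Points are libraries, crosses at 0 mark libraries without a listed peak, and black bars give the mean ± SD of groups with 2 peaks; at chr5:96630596–96631107 WT lies at 8.22 and 5.28 and E2A_HEB_dKO at 43 and 32.6.

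Libraries with E2A and HEB loss plus NICD were compared with E2A_HEB_dKO to see what active Notch changed without these E proteins. Accessibility rose at chr8:118079417–118079681 from 5.8 ± 1.7 to 28.9 ± 2.4 (2.17 ± 0.32, adjusted p = 0.000225), where WT held 21.4 ± 0, and at chr1:196769807–196769982 from 6.5 ± 0.52 to 32.3 ± 0.57 (2.14 ± 0.28, adjusted p = 6.8e-05), where WT held 18.8 ± 3.6. It fell at chr11:98341159–98341695 from 27.8 ± 7.9 to 5.54 ± 0.23 (-2.47 ± 0.38, adjusted p = 0.000618), where WT held 13.1 ± 5.6, and at chr19:5532620–5532787 from 43.2 ± 14 to 11.4 ± 1.6 (-2.06 ± 0.26, adjusted p = 3.29e-05), where WT held 10.6 ± 0.49. In total 4386 regions were higher and 3196 lower (7582 of 66639), with 4020 and 2706 called under both kinds of floor. The split was 6686 higher and 1136 lower with the values as deposited, and it turned to 2225 higher and 3144 lower over regions with a peak in all 4 libraries. The count was 2900 with a joining overlap of 50%, 2010 without E2A_HEB_dKO replicate 1, 2428 without E2A_HEB_dKO_NICD replicate 2 and 2640 without replicate 1 of that group.

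Compared with WT, E2A_HEB_dKO_NICD rose at chr15:5396168–5396680 from 10.8 ± 0.64 to 39.6 ± 3.9 (1.85 ± 0.20, adjusted p = 4.18e-06) and at chr13:99573737–99573976 from 7.64 ± 0.73 to 29.1 ± 1.4 (1.90 ± 0.32, adjusted p = 0.000831). The former was also at 38.8 ± 1.5 in E47KO, whereas the latter was at 9.64 ± 3.2 in E2A_HEB_dKO. Accessibility fell at chr5:120589278–120589547 from 40.2 ± 16 to 6.56 ± 2.4 (-2.64 ± 0.31, adjusted p = 1.27e-05, and 0.0964 with a joining overlap of 50%), where E2A_HEB_dKO held 7.72 ± 0.73. In total 2786 regions were higher and 4638 lower (7424 of 71420), with 2522 and 3784 called under both kinds of floor. The count was 3664 over regions with a peak in all 4 libraries (1641 higher and 2023 lower) and 4432 with a joining overlap of 50%. It was 2367 and 2507 without E2A_HEB_dKO_NICD replicates 1 and 2, and 4626 and 4213 without WT replicates 1 and 2.

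**Figure D4:**
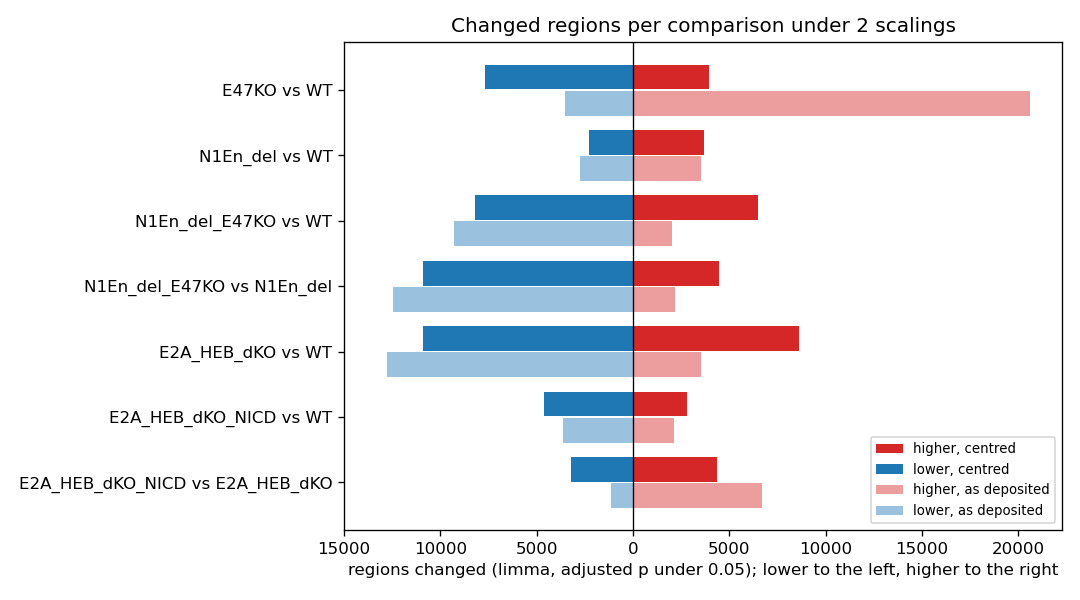
Numbers of regions called higher (right) and lower (left) with limma in 7 comparisons, with centred values (dark bars) and with values as deposited (light bars). For E47KO against WT the bars hold 3950 higher and 7682 lower with centring and 20611 higher and 3526 lower as deposited.

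Part of the regions that were lower without E2A and HEB were higher in the libraries with NICD. Both WT (18 and 26) and both E2A_HEB_dKO_NICD libraries (22 and 26) listed Y peaks, and the E2A_HEB_dKO libraries listed 0. Over the 35082 regions listed in all libraries, the replicates of E47KO and of N1En_del, which differed in Y peaks, correlated at 0.949 in each group. Groups whose libraries were alike in Y peaks reached 0.937 to 0.97, so Y peaks alone marked little difference there. An effect of NICD and any other difference in source that goes with these groups cannot be told apart. The simulation given below held no difference in source. Of the 10887 regions lower in E2A_HEB_dKO than in WT, 2479 (22.8%) were higher with NICD than in E2A_HEB_dKO, compared with 2% of the 46894 regions that did not change. Over the 10887 regions the median difference from WT was -1.22 in E2A_HEB_dKO and -0.68 with NICD, against -1.28 and -1.42 in a simulation without an NICD effect. A peak was listed in both E2A_HEB_dKO_NICD libraries for 69.1% of them and in both E2A_HEB_dKO libraries for 31.3%, against 45.3% and 38.2% in the simulation. The simulated gap arose without an NICD effect, and its cause was not tested. The centred floor relative to WT was -0.26 log2 units in E2A_HEB_dKO_NICD and -0.02 in E2A_HEB_dKO, which may add to the listed peaks with NICD in both. Of the 10887, 3230 (29.7%) were still called lower than WT with NICD, against 87.6% in the simulation. Of the 8622 regions higher in E2A_HEB_dKO, 2072 (24%) were lower with NICD than without it. The share of 22.8% fell to 9% without E2A_HEB_dKO_NICD replicate 1 and to 8% without its replicate 2, which left 1 library with NICD.

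The regions changed by E47 loss, by both deletions and by loss of E2A and HEB overlapped. E47KO and E2A_HEB_dKO shared 4969 lower and 2541 higher regions, where independent lists of these sizes would share 1298 and 410, and N1En_del_E47KO and E2A_HEB_dKO shared 5746 and 3898 (independent 1399 and 721). E47KO and N1En_del shared 1268 lower and 581 higher regions (independent 270 and 71). In a simulation of unchanged groups against the same WT libraries at most 1 region was called in a list and these 3 pairs shared 0, so this simulation says little about the overlap. Part of the excess may come from the shared WT libraries, which were not split, since each part would hold 1 library. The covariance of fold changes over the 35082 regions present in all libraries was 0.2 for E47KO and E2A_HEB_dKO, 0.233 for N1En_del_E47KO and E2A_HEB_dKO and 0.074 for E47KO and N1En_del, against 0.03 in each simulation, and the correlations were 0.73, 0.76 and 0.41, against 0.53, 0.53 and 0.52 in the simulations. As deposited, N1En_del_E47KO and E2A_HEB_dKO shared 1214 higher regions, and with 1 shared floor E47KO and N1En_del shared 2446 lower ones. The lower overlap of E47KO and E2A_HEB_dKO was 2055 without WT replicate 2 and 2023 without E2A_HEB_dKO replicate 1, and the higher one 1253 and 1215 without E47KO replicates 1 and 2 and 1685 without E2A_HEB_dKO replicate 1. For N1En_del_E47KO and E2A_HEB_dKO the counts of lower and higher regions were 2340 and 2346 without WT replicate 2, 3197 and 1363 without N1En_del_E47KO replicate 1, 1960 and 1253 without its replicate 2, and 2412 and 2250 without E2A_HEB_dKO replicate 1. For E47KO and N1En_del the lower count was 534 without WT replicate 2 and 289 without N1En_del replicate 1, and the higher count 374 and 347 without E47KO replicates 1 and 2 and 250 and 257 without N1En_del replicates 1 and 2.

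Whether the joint change of both deletions differed from the sum of the single changes was tested as an interaction. At chr2:26368915–26369174 the changes were -3.47 in E47KO, -3.76 in N1En_del and -3.85 with both, an interaction of 3.38 ± 0.47 (adjusted p = 0.00033). No peak was listed there in either N1En group, so both lay at the floor, and the term repeats the fall in E47KO and does not show whether the changes add up. Of 89767 regions, 1087 passed, 550 with a positive and 537 with a negative term, and 104 of them had a peak in all 8 libraries. The split was 401 positive and 9162 negative (9563) with the values as deposited, 1036 and 2760 (3796) with 1 shared floor, and 110 and 98 (208) over regions with a peak in all 8 libraries. The count was 716 over regions with a local fold of at least 8, 600 without E47KO replicate 2, 586 without N1En_del replicate 1, and 563 and 622 without N1En_del_E47KO replicates 1 and 2.

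Peaks present in both libraries of one group and absent from both of the other were counted without a test. E2A_HEB_dKO lost 10612 WT peaks, 18.4% of the 57611 listed in both WT libraries, and gained 4112. N1En_del_E47KO lost 6119 and gained 7030 against WT, and lost 8898 and gained 4886 against N1En_del. E47KO lost 3558 and gained 10428, N1En_del lost 3158 and gained 7956, and E2A_HEB_dKO_NICD lost 4477 and gained 6212. With NICD, 9770 peaks were gained and 1850 lost against E2A_HEB_dKO. E2A_HEB_dKO had the shortest lists, and with lists cut to equal length it lost 6172 WT peaks, and 4557 peaks were gained and 3743 lost with NICD. E47KO then gained 5268 peaks and N1En_del 4472. The other 2 splits of the 4 libraries of a comparison gave between 545 and 3076 regions, so that the 3558 regions lost in E47KO, the 3158 lost in N1En_del and the 1850 lost with NICD lay within 1.5 times the highest other split of their own comparison (3046, 3076 and 1729). Counting only peaks of at least 9.1 lowered the 14 counts to between 506 and 3790, and a local fold of at least 8 lowered those that moved by over 1.5 times to between 751 and 6388. With a joining overlap of 50% the loss with NICD was 3278. Leaving out any library of a comparison raised them, since fewer libraries had to hold or lack the peak, to between 3182 and 21553 for lost peaks and between 5759 and 25325 for gained peaks.

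Regions without a peak in all libraries with an allele were counted, since a deleted segment can give no peak, although a missing peak does not show a deletion. The 4 libraries with the N1En deletion lacked a peak in 23 regions that all 8 other libraries listed, among them chr2:26368915–26369174, and 58 of the 495 splits of the libraries into 4 and 8 gave at least as many. The 4 libraries of E47KO and N1En_del_E47KO lacked 6 such regions (191 splits gave as many). The 8 libraries set against them include the 4 with floxed Tcf3, the gene that makes E47. A peak lost in those too was not counted, so the 6 regions do not measure the effect of E47 loss. The 4 libraries with floxed Tcf3 and Tcf12 lacked 327, more than any other split (282 at most, WT with N1En_del). Counting only peaks of at least 9.1, the 3 counts were 3, 1 and 37, and the split of WT with N1En_del reached 44. For the N1En deletion the count was 35 and 37 without WT replicates 1 and 2, 57 and 49 without N1En_del replicates 1 and 2, 39 and 53 without N1En_del_E47KO replicates 1 and 2 and 40 without E2A_HEB_dKO replicate 1. For E47 it was 31 without E47KO replicate 2, 10 without either N1En_del library, 12 without N1En_del_E47KO replicate 2, and 52 and 18 without E2A_HEB_dKO replicates 1 and 2. For the floxed alleles it was 524 and 686 without E2A_HEB_dKO_NICD replicates 1 and 2.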

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

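The interaction test and the values as deposited were planned, and the prediction for the minimum fold over the local background was written before its result. The tests of the other explanations were chosen after the result was seen, as was the use of the values as deposited to weigh the balance in E47KO and of splits that keep groups whole. A difference between groups marked the regions whose change with both deletions differed from the sum of the single changes: 1087 passed the test of the interaction term. The same rule marked the 3 regions that follow. At chr18:53904659–53904816 the term was 8.66 ± 0.32 (adjusted p = 1.26e-13), with 58.9 and 47.5 in WT, 73.9 and 71.8 in N1En_del_E47KO and no peak listed in E47KO or N1En_del, whose nearest peaks lay 384 bp away at 95.8 and 70.2. At chr10:79599797–79600288 it was -6.18 ± 0.43 (adjusted p = 1.06e-08), with 51.6 and 59.1 in E47KO, 31.7 and 23.1 in N1En_del, no peak listed in WT or N1En_del_E47KO, and a local fold of 4.9 where listed, near the lowest of the lists (4). At chr2:26368915–26369174 it was 3.38 ± 0.47, with no peak listed in N1En_del or N1En_del_E47KO. All 3 sizes depend on the floor given to libraries without a peak, and the first 2 lie near a listing limit, so they do not show a loss or gain of accessibility. At the third both N1En groups lay at the floor, so its term repeats the fall in E47KO and does not show whether the changes add up.

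More regions were lower than higher in E47KO against WT, 7682 against 3950. A lower detection floor of the E47KO libraries was argued against as the whole cause, since lower regions still made up 59.3% of the changes (6368 of 10740) with 1 floor shared by all libraries. Scaling remains open: with the values as deposited the lower share was 14.6%, because centring removed offsets of 0.46 and 0.54 log2 units in the E47KO libraries. The counts of listed peaks also ran the other way, with 10428 gained and 3558 lost in E47KO against WT. They are not a second line of evidence, since the E47KO lists were longer (78165 and 93785 peaks, against 74897 and 67339 in WT). With lists cut to equal length the gain was smaller, as given above. Whether E47 loss lowers or raises more regions may therefore rest on the choice of scaling. A biological shift of all regions by E47 loss was not tested, since it needs an outside standard.

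Tall peaks listed in both libraries of one group and in neither of the other numbered 4031 at a height of at least 20 over the 7 comparisons in both directions, in 2181 distinct regions, since a region counts once in each comparison. The minimum distance between peaks of one list remains open for part of them, since 23.9% lay within 500 bp of another peak of the group without them, against 8.6% of the 269243 kept entries, counted alike (30246 distinct regions). The minimum fold over the local background also remains open: of the 1991 that stood alone, 57.7% had a local fold under 6 where listed, against 2.1% of kept peaks. The other 843 of the 1991 had a local fold of at least 6, with the largest share for WT peaks missing in E2A_HEB_dKO (143 of 222), and 1078 that lay between 500 and 1000 bp from another peak were not classed. No biological explanation was tested for the 843, which include peaks missing in WT.

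For chromosome 12, tall regions were those with at least 9.1 in each of the 8 libraries outside the floxed groups. Of 26 tall regions in chr12:18000000–25000000, 10 had no peak in either E2A_HEB_dKO library, against 142 of 25910 elsewhere (Fisher exact p = 1.74e-16, an interval chosen after its values were seen). Loss of one unbroken segment of DNA was argued against, because 15 regions between the first and last missing one kept a peak in both E2A_HEB_dKO libraries. The minimum distance between peaks was also argued against, with the nearest E2A_HEB_dKO peak at least 69164 bp away. A difference in DNA sequence or copy number between mouse lines and a loss of accessibility cannot be told apart from the 38.5% of regions missing, because the floxed alleles and any difference of line go together in these groups. In E2A_HEB_dKO_NICD, 5 of the 10 were missing too and 5 had a peak in both libraries at 12.4% to 49.3% of WT.

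Libraries of one group share missing peaks, so the allele counts were set beside the 15 splits of the libraries into 4 and 8 that keep groups whole, which are too few for a share under 0.05. As many regions were found in 8 of them for the N1En deletion (23, highest other 327), in 11 for E47 (6, highest other 327) and in 1, the real one, for the floxed alleles (327, highest other 282). The count for E47 has the limit given above, since libraries with floxed Tcf3 stood on the other side. The highest other for the floxed alleles was WT with N1En_del, the groups without a change to E47 or floxed Tcf3 and Tcf12. All other groups carry such a change, so this split is also a contrast of genotypes. It cannot show what a split unrelated to genotype would give. With peaks of at least 9.1 the split of WT with N1En_del exceeded the real split (44 against 37).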

How the results depend on the processing

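The alternatives of 1 shared floor, joining by an overlap of 1 bp, regions with no other region within 500 bp, autosomes and a local fold of at least 8 were chosen after the result was seen, as were the tests that left out libraries for the overlaps and the allele check. The filter on low values, the overlap of 1 bp and autosomes kept every count of changed regions within 1.5 times, and so did the replicate number as a block (935 for the interaction to 19394 for E2A_HEB_dKO against WT). The deviations of libraries with the same number correlated between -0.03 and 0.13 over 15 pairs of groups, 1 above 0.1, which gave little sign of a batch shared by number. A batch that follows genotype or crosses the numbers cannot be seen this way. The planned edgeR count test was not run, because no library totals were recorded, and neither were gene lists and motifs, which need mm9 annotation and sequence. Of the values for named regions under the alternatives, 591 kept their call, 18 were weaker, 2 were stronger and 0 reversed. Depth limits which peaks are listed, since the lowest peak needed 14 to 21 tags. Where no cause is given below, the cause was not tested.

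With the values as deposited, the changed regions numbered 24137 for E47KO against WT and 9563 for the interaction. Over regions with a peak in all libraries compared, which leaves fewer regions, the changed regions numbered 6480 for E47KO against WT, 2324 for N1En_del against WT, 7681 for N1En_del_E47KO against N1En_del, 11354 for E2A_HEB_dKO against WT, 3664 for E2A_HEB_dKO_NICD against WT and 208 for the interaction. With a joining overlap of 50%, the changed regions numbered 7360 for E47KO against WT, 3184 for N1En_del against WT, 7357 for N1En_del_E47KO against WT, 8418 for N1En_del_E47KO against N1En_del, 10723 for E2A_HEB_dKO against WT, 4432 for E2A_HEB_dKO_NICD against WT and 2900 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. With 1 shared floor, the changed regions numbered 11358 for N1En_del against WT and 3796 for the interaction. With a local fold of at least 8, the changed regions numbered 716 for the interaction.

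Counting only peaks of at least 9.1, which leaves fewer peaks, lost peaks numbered 816 for E47KO against WT, 568 for N1En_del against WT, 1637 for N1En_del_E47KO against WT, 1658 for N1En_del_E47KO against N1En_del, 2414 for E2A_HEB_dKO against WT, 839 for E2A_HEB_dKO_NICD against WT and 506 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. The gained peaks numbered 3790 for E47KO against WT, 1399 for N1En_del against WT, 1227 for N1En_del_E47KO against WT, 756 for N1En_del_E47KO against N1En_del, 1307 for E2A_HEB_dKO against WT, 1430 for E2A_HEB_dKO_NICD against WT and 1797 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. With a local fold of at least 8, which also leaves fewer, lost peaks numbered 2195 for E47KO against WT, 1835 for N1En_del against WT, 3668 for N1En_del_E47KO against WT, 5173 for N1En_del_E47KO against N1En_del, 2962 for E2A_HEB_dKO_NICD against WT and 751 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. The gained peaks numbered 5361 for E47KO against WT, 4535 for N1En_del against WT, 3729 for N1En_del_E47KO against WT, 2579 for N1En_del_E47KO against N1En_del, 1706 for E2A_HEB_dKO against WT, 3187 for E2A_HEB_dKO_NICD against WT and 6388 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. With lists cut to equal length, lost peaks numbered 6172 for E2A_HEB_dKO against WT and 3743 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. The gained peaks numbered 5268 for E47KO against WT, 4472 for N1En_del against WT and 4557 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. With a joining overlap of 50%, lost peaks numbered 3278 for E2A_HEB_dKO_NICD against E2A_HEB_dKO.

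The regions shared by comparisons with WT numbered, with the values as deposited, 3275 for E47KO and N1En_del_E47KO (lower), 300 for N1En_del and N1En_del_E47KO (higher), 2081 for N1En_del and E2A_HEB_dKO (lower), 275 for N1En_del and E2A_HEB_dKO (higher), 1533 for N1En_del and E2A_HEB_dKO_NICD (lower), 394 for N1En_del and E2A_HEB_dKO_NICD (higher), 1214 for N1En_del_E47KO and E2A_HEB_dKO (higher), 582 for N1En_del_E47KO and E2A_HEB_dKO_NICD (higher) and 850 for E2A_HEB_dKO and E2A_HEB_dKO_NICD (higher). With 1 shared floor they numbered 2446 for E47KO and N1En_del (lower), 2879 for N1En_del and N1En_del_E47KO (lower), 2748 for N1En_del and E2A_HEB_dKO (lower) and 2053 for N1En_del and E2A_HEB_dKO_NICD (lower). The share of regions higher with NICD was 24% with the values as deposited, 29.1% with stricter peaks, 21.8% with 1 shared floor, 24.1% over regions with no other region within 500 bp and 27.2% with a local fold of at least 8. With stricter peaks the allele check gave 3 regions for N1En, 1 for E47 and 37 for the floxed alleles.

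With each library left out in turn an arm kept 1 library, which was assumed to vary like the other groups. The changed regions then numbered 5748 to 8673 for E47KO against WT, 1883 to 4115 for N1En_del against WT, 4120 to 12300 for N1En_del_E47KO against WT, 3115 to 8429 for N1En_del_E47KO against N1En_del, 7645 to 14506 for E2A_HEB_dKO against WT, 2367 to 4626 for E2A_HEB_dKO_NICD against WT, 2010 to 5532 for E2A_HEB_dKO_NICD against E2A_HEB_dKO and 563 to 1538 for the interaction. Lost peaks numbered 4604 to 9597 for E47KO against WT, 4933 to 9824 for N1En_del against WT, 7724 to 14021 for N1En_del_E47KO against WT, 10961 to 21553 for N1En_del_E47KO against N1En_del, 13315 to 21332 for E2A_HEB_dKO against WT, 6467 to 12439 for E2A_HEB_dKO_NICD against WT and 3182 to 5239 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. Gained peaks numbered 13823 to 25325 for E47KO against WT, 10847 to 20344 for N1En_del against WT, 9636 to 15247 for N1En_del_E47KO against WT, 7350 to 11514 for N1En_del_E47KO against N1En_del, 5759 to 8487 for E2A_HEB_dKO against WT, 9145 to 14896 for E2A_HEB_dKO_NICD against WT and 12875 to 20589 for E2A_HEB_dKO_NICD against E2A_HEB_dKO. These counts of peaks rose because fewer libraries had to hold or lack a peak. The share with NICD ranged from 8% to 30.6%, and the allele check gave 26 to 57 for N1En, 7 to 52 for E47 and 338 to 686 for the floxed alleles. Shared regions, lower and then higher, numbered 289 to 1227 and 250 to 796 for E47KO and N1En_del, 1625 to 4065 and 916 to 2122 for E47KO and N1En_del_E47KO, 2023 to 3681 and 1215 to 2097 for E47KO and E2A_HEB_dKO, 801 to 2214 and 418 to 1044 for E47KO and E2A_HEB_dKO_NICD, 370 to 1083 and 246 to 931 for N1En_del and N1En_del_E47KO, 320 to 964 and 219 to 840 for N1En_del and E2A_HEB_dKO, 235 to 796 and 265 to 738 for N1En_del and E2A_HEB_dKO_NICD, 1960 to 4443 and 1253 to 3944 for N1En_del_E47KO and E2A_HEB_dKO, 735 to 2070 and 411 to 1281 for N1En_del_E47KO and E2A_HEB_dKO_NICD and 1228 to 2233 and 506 to 1465 for E2A_HEB_dKO and E2A_HEB_dKO_NICD.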

Other observations

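All tests in this part were chosen after the result was seen. Fold changes that share no library were set side by side, with r over the 35082 regions listed in all libraries and shared calls over the 56599 to 65121 regions tested in both. The change from N1En_del to N1En_del_E47KO followed that from WT to E47KO (r = 0.54), with 2355 regions lower and 1092 higher in both, where independent lists would share 452 and 217. It also followed the change from WT to E2A_HEB_dKO (r = 0.58), with 2947 lower and 2131 higher in both (independent 823 and 531). The change with NICD ran opposite to that in E47KO (r = -0.49), with 18 regions lower and 69 higher in both (independent 205 and 212). It had r = 0.02 with the change in N1En_del, with 121 regions lower and 276 higher in both (independent 57 and 120). The change in N1En_del had r = 0.2 with that from E47KO to N1En_del_E47KO.

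Changed regions lay close together in some 100 kb windows. The window test treated the regions of a window as independent, which neighbouring regions need not be. Its p-values were adjusted within each comparison and direction, not over all of them. In chr17:13800001–13900000, 7 of 11 regions were higher in E2A_HEB_dKO_NICD than in E2A_HEB_dKO (adjusted p = 0.0196 over 14160 windows), and 8 of 11 were lower in E2A_HEB_dKO than in WT (adjusted p = 0.249). In it chr17:13852598–13852859 held 58.2 ± 1.6 in WT, 35.6 ± 0.71 in E47KO, 25.8 ± 0.64 in N1En_del, 15 ± 2.4 in N1En_del_E47KO, 18.6 ± 2.8 in E2A_HEB_dKO and 38.2 ± 2.6 with NICD. In chr10:22000001–22100000, 6 of 7 regions were higher in E47KO (adjusted p = 0.00174), and in chr11:8600001–8700000, 7 of 7 were lower in N1En_del_E47KO than in N1En_del (adjusted p = 0.0173).

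A tall difference between groups was at chr1:24619885–24620036, with 1990 ± 368 in E2A_HEB_dKO, 2160 ± 248 in E2A_HEB_dKO_NICD and no peak listed in the other 8 libraries. The rule fixed beforehand ranks it 1 among the rises of both groups against WT. In WT the nearest peak lay 20826 bp away, and the local fold was 128.75 and 377.47 where listed. Neither listing limit therefore applies to WT. The nearby chr1:24619499–24619669, 376 bp away, held 1100 ± 794 in E2A_HEB_dKO and 314 ± 30.6 in E2A_HEB_dKO_NICD, against 15.9 ± 5.8 in E47KO, 9.16 ± 2.47 in N1En_del, 6.56 ± 1.96 in N1En_del_E47KO and no peak listed in WT. In E47KO, N1En_del and N1En_del_E47KO this nearby peak lies within the distance weighed as a listing limit. The E2A_HEB_dKO and E2A_HEB_dKO_NICD lists held both peaks at that distance, which argues against the minimum distance as the reason for the missing peak. The heights at chr1:24619885–24620036 stood far above the median peak of these lists. Those medians were 13.3 and 10.8 in E2A_HEB_dKO and 11.4 and 11.2 in E2A_HEB_dKO_NICD. Whether the tags counted there were mapped to the right place was not tested. The values therefore do not show a gain of accessibility.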
